A study of Mus musculus with 23 samples.

How the data were processed

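RNA sequencing had been done on 23 primary brain tumours of mice from a Sleeping Beauty transposon screen, with 1 library per tumour. The labels give total RNA, a TruSeq RNA library kit and the model name Nestin Cre Sleeping Beauty for each tumour. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), to which a constant of 0.1 had been added. Per the submitters' processing notes, STAR and Cufflinks 2.0.1.3 were used with FastQC 0.11.2 and the mm10 genome. The gene annotation and the scaling option are not stated. The constant was subtracted before any other step, since the digits of the values showed it. Between 10.0 and 10.1, for instance, 89.8% of the values had more than 6 significant digits as deposited and 0.0% had more after the subtraction.

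The table had 23995 rows, of which 1 named no gene. Of the other 23994 genes, 22690 matched a GENCODE M21 symbol and 948 matched 1 older symbol in the RefSeq annotation. Coordinates are from GENCODE M21 on mm10. The table holds no read counts. The depth of each library was therefore estimated from the spacing of low FPKM values, over 3308 genes with transcripts of 800 to 6000 bp less 150 bp at the ends. In each tumour, 78.9% to 85.7% of the low values lay within 0.15 of a whole number of fragments at the estimated depth. The estimate is not a count of mapped reads, and it gives no counting interval.

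Tumours were grouped by the gene name in their titles. This gave 18 p53, 2 PTEN, 1 GFAP-PTEN and 1 Triple tumour. The title of 1 tumour reads PREN, which matched none of these, and it entered no comparison. Whether it is another PTEN tumour is not stated. The labels do not state which alleles the titles stand for, nor that each tumour came from a different animal, so each p value measures only the spread between these tumours. Of the 253 pairs of tumours, the closest were p53 308 and p53 566, with a correlation of 0.980 across genes, which are not independent replicates. At most 1 value above 0 was identical in any pair.

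The PTEN tumours were compared with the p53 tumours by limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended and robust empirical Bayes step. Genes with at least 1 FPKM in at least 2 of the compared tumours were tested, two-sided, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry. The 34 lists cover p53 targets, PI3K and FoxO output, sterol and fatty acid synthesis, glycolysis and hypoxia, cell cycle, MYC targets, SHH, WNT and Notch pathways, brain regions and lineages, neural, glial, immune, vascular and other cell types, immediate early genes and tumour drivers. Of these, 32 had at least 3 tested members. The lymphocyte list and the mitochondrially encoded list had fewer and were not tested. The same limma fit compared the 4 tumours titled p53 with the 14 titled P53, as a check for a batch behind the spelling. It was repeated with the 3 clusters described below as a block, a choice made after the data had been seen.

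Within the p53 tumours, a list score was the mean log2(FPKM + 1) of the tested members. The 14 relations between scores had been planned over all 18 tumours. The tumours fell into 3 clusters by hierarchical clustering of their log2 values, so no correlation over all 18 is given. It was computed within the cluster of 11, a choice made after the data had been seen. Pearson and Spearman coefficients were tested by 100000 two-sided permutations, or by all orderings where fewer than 10 tumours were used, with SciPy 1.17.1 in Python 3.11.15. The GFAP-PTEN and Triple tumours have no replicate. Their values were set beside the range of the p53 tumours. The share of genes outside that range was also computed for each p53 tumour against the other 17, added after the data had been seen. For each list, the median log2 difference from the p53 mean was placed among 10000 random lists of the same size, matched on mean expression in 20 bins.

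The groups, tests, lists and alternatives were fixed before the data were examined, as was the rule for naming genes. For PTEN against p53 it took genes past the threshold whose higher group mean was at least 5 FPKM, up to 12 in each direction, and up to 4 members of each list described, those with the smallest p. For the p53 tumours it took the 12 genes with the largest SD of log2(FPKM + 1) among those with a mean of at least 5 FPKM, leaving out Xist, Tsix and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. For each single tumour it took the 8 genes farthest above and the 8 farthest below the p53 range. A gene above had to reach 5 FPKM in the tumour, and a gene below had to reach it in every p53 tumour. Trp53, Pten, Gfap, Nes and Foxr2 were named throughout. Mfi2, Bdkrb2, Gm10052, Ibsp, Arhgap36 beyond its place among the variable genes, the ribosomal protein genes and the lineage markers used to describe the clusters were chosen after their values had been seen.

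The fits were tested on simulated data with 50 genes changed at each size. For 2 tumours against 18, the fit found 28% of genes changed by 1 on the log2 scale, 66% of those changed by 2, 86% by 3 and 94% by 4. It also called 11 unchanged genes among 148 calls. For 4 against 14 it found 44%, 82%, 100% and 100%, with 14 unchanged genes among 177 calls. A list shifted in the simulation had a camera p of 3.8e-17 in the first design and 3.35e-33 in the second, and a random list 0.784 and 0.471. Each simulated gene was drawn independently, without the clusters of the real tumours and without genes that vary together. The changed genes also had higher p53 levels than the genes reported below as past the threshold. The rates of found and false calls therefore do not carry over to the real data. Alternatives covered the pseudocount, the filter, the scaling, the variance model, weights per tumour, the composition of each group and leaving out each tumour. The near-identical copies of 1 gene were found with BLAST 2.17.0.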

Results

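Gene expression was measured by RNA sequencing in 23 primary mouse brain tumours. They came from a Sleeping Beauty screen, in which a mobile DNA element inserts at random and can alter genes that drive tumours. The titles name 18 tumours p53, 2 PTEN, 1 GFAP-PTEN and 1 Triple, while 1 more tumour could not be placed. p53, encoded by Trp53, and PTEN are tumour suppressors, and GFAP is an intermediate filament protein of astrocytes. The labels do not say what Triple combines. The estimated depth had a median of 23.6 M fragments per tumour. It was lowest in GFAP-PTEN-49, at 10.2 M, and highest in p53 546, at 30.8 M. The PTEN tumours had 23.0 and 26.1 M, and Triple363 had 23.0 M. Between 12223 and 13664 genes reached 1 FPKM in each tumour, and 3812 genes were listed at 0 in all of them.

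The 2 PTEN tumours were compared with the 18 p53 tumours, the only titles with more than 1 tumour. The labels state no purpose for this comparison. The p53 mean and spread mix the sets of p53 tumours described below, which this fit did not separate. Gli1 and Atoh1, markers of the largest set, had 37.0 and 26.5 FPKM in PTEN-241 and 137 and 86.1 FPKM in PTEN-468. PTEN-241 also had 1608 FPKM of Snap25, which marks the set with low Mki67. Fam78a and Fam115c were higher in both PTEN tumours than in every p53 tumour. Fam78a averaged 6.96 FPKM in the PTEN tumours (5.45 and 8.47) and 1.24 ± 0.553 FPKM in the p53 tumours (SD, n = 18, highest 2.09). Its log2 difference was 1.84 ± 0.29 (SE, limma adjusted p = 0.0299). Fam115c, named Tcaf2 in the current annotation and known as a regulator of TRP ion channels, averaged 8.73 FPKM in the PTEN tumours (4.09 and 13.4) and 0.840 ± 0.765 FPKM in the p53 tumours (SD, n = 18, highest 2.92). Its log2 difference was 2.31 ± 0.40 (SE, limma adjusted p = 0.0418). Mfi2 (now Meltf), which encodes the iron-binding protein melanotransferrin, and the bradykinin receptor gene Bdkrb2 also passed, at lower levels. Mfi2 averaged 2.72 FPKM against 0.159 ± 0.195 FPKM (SD, n = 18), and Bdkrb2 averaged 2.71 FPKM against 0.339 ± 0.377 FPKM (SD, n = 18). On mm10, Fam78a lies on chromosome 2 from 32050055 to 32084857, Fam115c on chromosome 6 from 42623016 to 42645254, Mfi2 on chromosome 16 from 31878810 to 31899020 and Bdkrb2 on chromosome 12 from 105563226 to 105595237, and all are annotated as protein-coding genes.

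These 4 genes were the only ones of 14976 tested to pass, and 0 genes passed with a lower level in the PTEN tumours. At an unadjusted p under 0.05 there were 310 genes, where uniform p values would give 748.8. The count changed with single tumours and with the log scale. It was 0 with a pseudocount of 0.1 FPKM, 9 without PTEN-241 and 18 without PTEN-468, and none of those 18 were among the 4. It was also 0 without any one of p53 272, 581, 176, 523, 531, 546, 634, 690 or 691, 1 without p53 184 or p53 593, and 2 without p53 301. The differences themselves moved little when a p53 tumour was left out, with log2 values of 2.28 to 2.38 for Fam115c and 1.81 to 1.87 for Fam78a. They were 3.33 and 2.49 with a pseudocount of 0.1 FPKM, 3.06 and 2.12 without PTEN-241, and 1.56 and 1.57 without PTEN-468.

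The genes that the titles name did not pass the test. Trp53 averaged 90.4 FPKM in the PTEN tumours (65.9 and 115) and 65.3 ± 35.3 FPKM in the p53 tumours (SD, n = 18). Pten averaged 13.8 FPKM (12.2 and 15.4) against 16.5 ± 3.68 FPKM. Gfap averaged 126 FPKM (118 and 134) against 225 ± 287 FPKM. Nes, which encodes the progenitor filament protein nestin, averaged 86.8 FPKM (38.7 and 135) against 28.6 ± 32.6 FPKM, with an unadjusted limma p of 0.0821. Foxr2, a forkhead transcription factor gene, averaged 0.117 FPKM against 4.21 ± 6.66 FPKM. Each of these 5 had an adjusted p of 1.0.

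**Figure D1:**
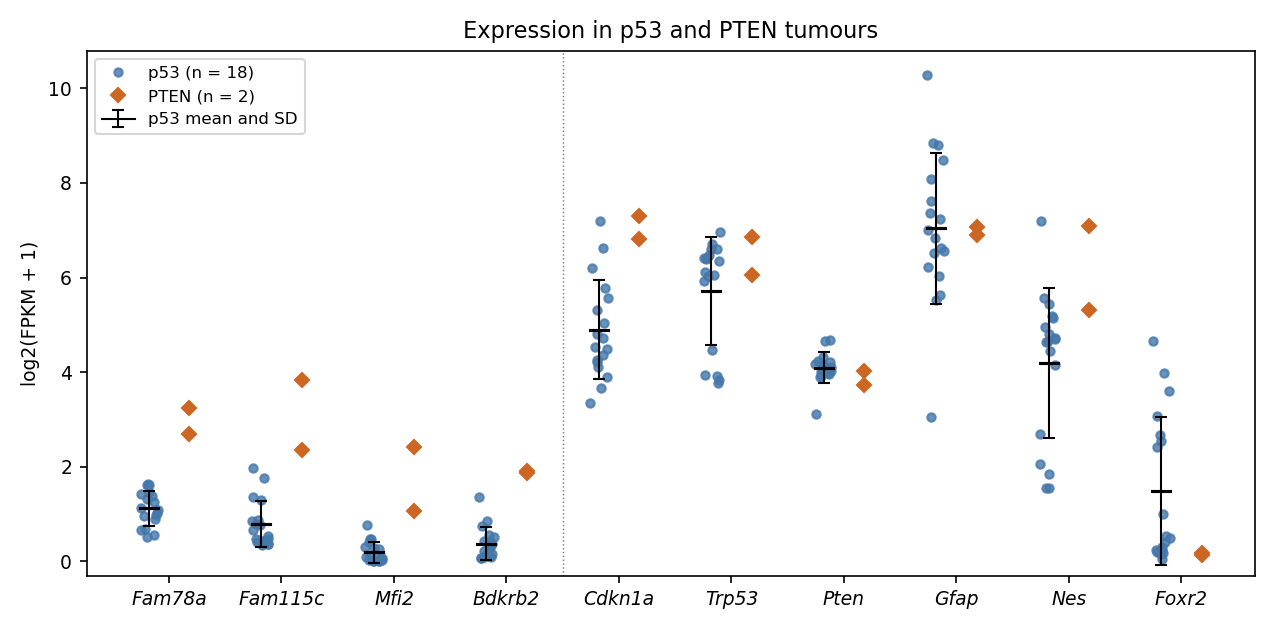
Expression as log2(FPKM + 1) of the 4 genes past the threshold (left of the dotted line) and of 6 other named genes in the 18 p53 tumours (circles, with mean and SD) and the 2 PTEN tumours (diamonds). Fam78a reached at most 2.09 FPKM in a p53 tumour and at least 5.45 FPKM in a PTEN tumour, while Trp53 and Pten overlapped between the titles.

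Genes of the p53 response were higher on average in the PTEN tumours. Of 23 tested p53 target genes, 22 were higher and 1 was lower, with a median log2 difference of 0.46 (camera adjusted p = 1.57e-07). This was the 1 list of 32 that also passed with an estimated correlation (adjusted p = 0.0321). By fry its adjusted p was 0.194. No member passed, whether adjusted over all genes tested or adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, averaged 134 FPKM in the PTEN tumours (112 and 157) and 38.3 ± 35.3 FPKM in the p53 tumours (SD, n = 18). The highest p53 tumour had 145 FPKM of Cdkn1a. Aen averaged 17.9 against 10.6 ± 3.31 FPKM, Ccng1 33.5 against 21.2 ± 9.03 FPKM and Tnfrsf10b 1.35 against 0.620 ± 0.324 FPKM. The list score of PTEN-468 (4.29) lay above every p53 tumour. That of PTEN-241 (3.93) lay below p53 184, 579, 176 and 523 (3.98, 3.96, 3.95 and 3.94). The lowest p53 scores, 3.02 to 3.34, were in p53 308, 566, 593 and 701, and they lower the p53 mean. By camera with the preset correlation, the list still passed when these tumours were left out, an alternative added after the data had been seen. Without PTEN-468 the adjusted p of this list was 0.0635, and over all alternatives it ranged from 3.61e-08 to 0.194.

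Muscle genes were high in 1 of the PTEN tumours and in 1 p53 tumour. All 5 tested members of the skeletal muscle and bone list were higher on average in the PTEN tumours, with a median log2 difference of 1.71 (camera adjusted p = 3.17e-08, and adjusted p = 0.0737 with an estimated correlation). Of these, 4 passed when adjusted over the list alone and 0 over all genes tested. The myosin light chain gene Mylpf had 54.4 FPKM in PTEN-241, 4.69 FPKM in PTEN-468 and 59.1 FPKM in p53 184, beside a p53 median of 0.910 FPKM. The muscle actin gene Acta1 had 51.1 FPKM in PTEN-241, 3.93 FPKM in PTEN-468 and 60.6 FPKM in p53 184. Tnnt3 averaged 5.98 FPKM in the PTEN tumours against 1.39 ± 3.94 FPKM (SD, n = 18), and Ckm 2.94 against 0.590 ± 1.77 FPKM. Without PTEN-241 the adjusted p of this list was 0.607, and over all alternatives it ranged from 1.86e-14 to 0.607.

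Proliferation genes and Notch pathway genes were higher on average in the PTEN tumours. Neither list passed without 4 p53 tumours with less than 10 FPKM of the proliferation gene Mki67. All 30 cell cycle genes were higher, with a median log2 difference of 0.79 (camera adjusted p = 1.37e-04, and adjusted p = 0.947 with an estimated correlation). Ccne1 averaged 15.1 FPKM in the PTEN tumours against 9.70 ± 2.96 FPKM (SD, n = 18), Rrm2 115 against 58.8 ± 44.6 FPKM, Mcm6 136 against 87.3 ± 60.1 FPKM and Mcm2 81.5 against 52.5 ± 36.5 FPKM. Of the 12 Notch pathway genes, 10 were higher, with a median log2 difference of 0.39 (adjusted p = 0.0207, and adjusted p = 0.747 with an estimated correlation). The ligand genes Jag1 and Dll3 averaged 25.4 and 105 FPKM in the PTEN tumours, against 7.80 ± 6.56 and 18.3 ± 18.7 FPKM. Hes1 averaged 28.3 against 15.0 ± 10.5 FPKM, and Hey2 went the other way, at 1.05 against 3.28 ± 3.51 FPKM. In SD from the mean of the 18 p53 tumours, the Notch score was 0.105 in PTEN-241 and 1.46 in PTEN-468. The cell cycle score was 0.106 and 0.867. No member of either list passed when adjusted over the list alone. Without those 4 p53 tumours, an alternative added after the data had been seen, the adjusted p was 0.894 for cell cycle genes and 0.291 for Notch genes. Without PTEN-468 it was 0.815 for cell cycle genes and 0.999 for Notch genes, and over all alternatives it ranged from 8.79e-07 to 0.968 and from 0.000646 to 0.999.

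Genes of glycolysis and hypoxia, of blood vessels and of the immediate early response were also higher as groups. Of 17 glycolysis and hypoxia genes, 16 were higher, with a median log2 difference of 0.46 (camera adjusted p = 1.75e-04, and adjusted p = 0.615 with an estimated correlation). The lactate dehydrogenase gene Ldha averaged 314 FPKM (239 and 390) against 200 ± 89.3 FPKM (SD, n = 18) and Pgk1 54.6 (54.0 and 55.1) against 36.9 ± 18.9 FPKM. Car9 averaged 4.94 (0.970 and 8.91) against 1.31 ± 1.87 FPKM and Adm 7.39 (5.09 and 9.68) against 4.89 ± 10.6 FPKM. Of 9 pericyte and smooth muscle genes, 8 were higher, with a median of 0.37 (adjusted p = 0.00203, and adjusted p = 0.581 with an estimated correlation). They included the smooth muscle actin gene Acta2, at 16.2 against 4.97 ± 5.10 FPKM, Rgs5, at 43.5 against 19 ± 11.1 FPKM, Tagln, at 12.1 against 7.74 ± 7.62 FPKM, and Abcc9, at 4.16 against 2.93 ± 1.16 FPKM. Of 11 endothelial genes, 10 were higher, with a median of 0.42 (adjusted p = 0.00271, and adjusted p = 0.661 with an estimated correlation). Eng averaged 18.5 against 10.6 ± 6.15 FPKM, Esam 17.5 against 11.5 ± 5.15 FPKM, Kdr 5.67 against 3.69 ± 1.70 FPKM and Emcn 7.0 against 4.91 ± 3.81 FPKM. Of 12 immediate early and stress genes, 10 were higher, with a median of 0.36 (adjusted p = 0.0207, and adjusted p = 0.615 with an estimated correlation). Atf3 averaged 4.45 (3.76 and 5.13) against 2.73 ± 1.66 FPKM and Jun 50.3 (42.3 and 58.2) against 40.2 ± 9.67 FPKM. Npas4 averaged 8.83 (0.691 and 17.0) against 1.97 ± 2.74 FPKM and Fosb 3.47 (0.303 and 6.64) against 0.980 ± 1.45 FPKM. For Npas4 and Fosb only 1 PTEN tumour was well above the p53 medians of 1.02 and 0.259 FPKM. No member of these 4 lists passed when adjusted over the list alone.

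The glycolysis and hypoxia call held with any single tumour left out (adjusted p at most 0.0277), and the other 3 calls each ended without 1 of the PTEN tumours. Without PTEN-468 the adjusted p was 0.999 for pericyte and 0.620 for endothelial genes, and without PTEN-241 it was 0.840 for immediate early genes. With a mean of at least 5 FPKM required it was 0.463 for immediate early genes. Over all alternatives, fry included, it ranged from 2.48e-09 to 0.968 for glycolysis and hypoxia, from 9.7e-06 to 0.999 for pericytes, from 1.53e-05 to 0.968 for endothelium and from 2.96e-05 to 0.968 for immediate early genes. By fry, 0 of the 32 lists passed.

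The other 24 lists did not pass. In the WNT pathway list (adjusted p = 0.0701) the secreted inhibitor gene Wif1 passed when adjusted over the list alone, at 0.0254, with 27.4 and 91.2 FPKM in the PTEN tumours against 7.05 ± 8.03 FPKM (SD, n = 18). In the list of embryonal and imprinted growth genes (adjusted p = 0.336) H19, an imprinted noncoding RNA, passed in the same way, at 0.0269, with 24.7 and 116 FPKM against 6.52 ± 9.98 FPKM. Both had an adjusted p of 1.0 over all genes tested. Progenitor and lineage lists had adjusted p values of 0.0766 for neural stem and progenitor genes, 0.0766 for the cerebellar granule lineage, 0.890 for immature neurons, 0.604 for mature neurons, 0.936 for astrocytes, 0.232 for oligodendrocyte progenitors, 0.918 for myelinating oligodendrocytes, 0.410 for choroid plexus and ependyma, and 0.898 for the photoreceptor program. Regional lists had 0.935 for forebrain and 0.936 for hindbrain genes. Signalling and growth lists had 0.115 for MYC targets, 0.458 for SHH pathway targets, 0.336 for PI3K and FoxO output, 0.525 for sterol and fatty acid synthesis, 0.140 for mesenchymal glioma genes and 0.918 for tumour driver genes. Lists of other cells had 0.898 for microglia and macrophages, 0.636 for neutrophils, 0.898 for interferon and antigen presentation, 0.525 for fibroblasts and matrix, and 0.816 for erythroid genes. With 1 PTEN tumour left out, 5 of these 24 lists passed. Without PTEN-468, mature neuron genes were higher (adjusted p = 8.41e-04) and so was the cerebellar granule lineage (0.0437), while oligodendrocyte progenitor genes were lower (0.0479). Without PTEN-241, mature neuron genes were lower (0.0277), and neural stem and progenitor genes (0.0116) and MYC target genes (0.00413) were higher. The 0.604 for mature neurons thus averages PTEN tumours that differed from the p53 tumours in opposite directions. The median, the mean and the test differed in sign for 7 lists, namely embryonal and imprinted, photoreceptor, forebrain, hindbrain, astrocyte, myelinating oligodendrocyte, and PI3K and FoxO genes.

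The 18 p53 tumours did not form 1 expression type. A set of 11 tumours had markers of sonic hedgehog signalling and of cerebellar granule precursors. In these 11 the hedgehog target Gli1 ranged from 48.9 to 256 FPKM and Mki67 from 57.8 to 105 FPKM. Atoh1, a granule precursor transcription factor gene, ranged from 35.9 to 190 FPKM in 9 of them, and had 2.83 FPKM in p53 523 and 1.0 FPKM in p53 546. A set of 3 tumours, p53 301, 579 and 581, had markers of oligodendrocyte progenitors, with Olig2 at 190 to 235 FPKM, Sox10 at 270 to 394 FPKM and Pdgfra at 114 to 298 FPKM, while Gli1 was at most 1.96 FPKM. The last 4 tumours, p53 308, 566, 593 and 701, had at most 9.80 FPKM of Mki67, together with the neuronal gene Snap25 at 1249 to 1897 FPKM and the myelin gene Mbp at 705 to 1261 FPKM.

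Regional markers separated these 4 tumours further. The Purkinje cell gene Pcp2 had 868 and 880 FPKM in p53 308 and p53 566, and Gabra6, a receptor gene of mature granule cells, had 297 and 281 FPKM. The forebrain genes Foxg1 and Tbr1 had 45.7 and 21.2 FPKM in p53 593, and 20.2 and 23.3 FPKM in p53 701. Across genes, pairs of tumours within a set correlated at 0.867 to 0.980, and pairs from different sets at 0.680 to 0.861. The same 11 tumours grouped together under each of 3 other ways of clustering. Trp53 ranged from 12.7 to 123 FPKM over the 18 tumours, Pten from 7.74 to 24.5 FPKM, Gfap from 7.35 to 1239 FPKM and Nes from 1.93 to 146 FPKM.

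**Figure D2:**
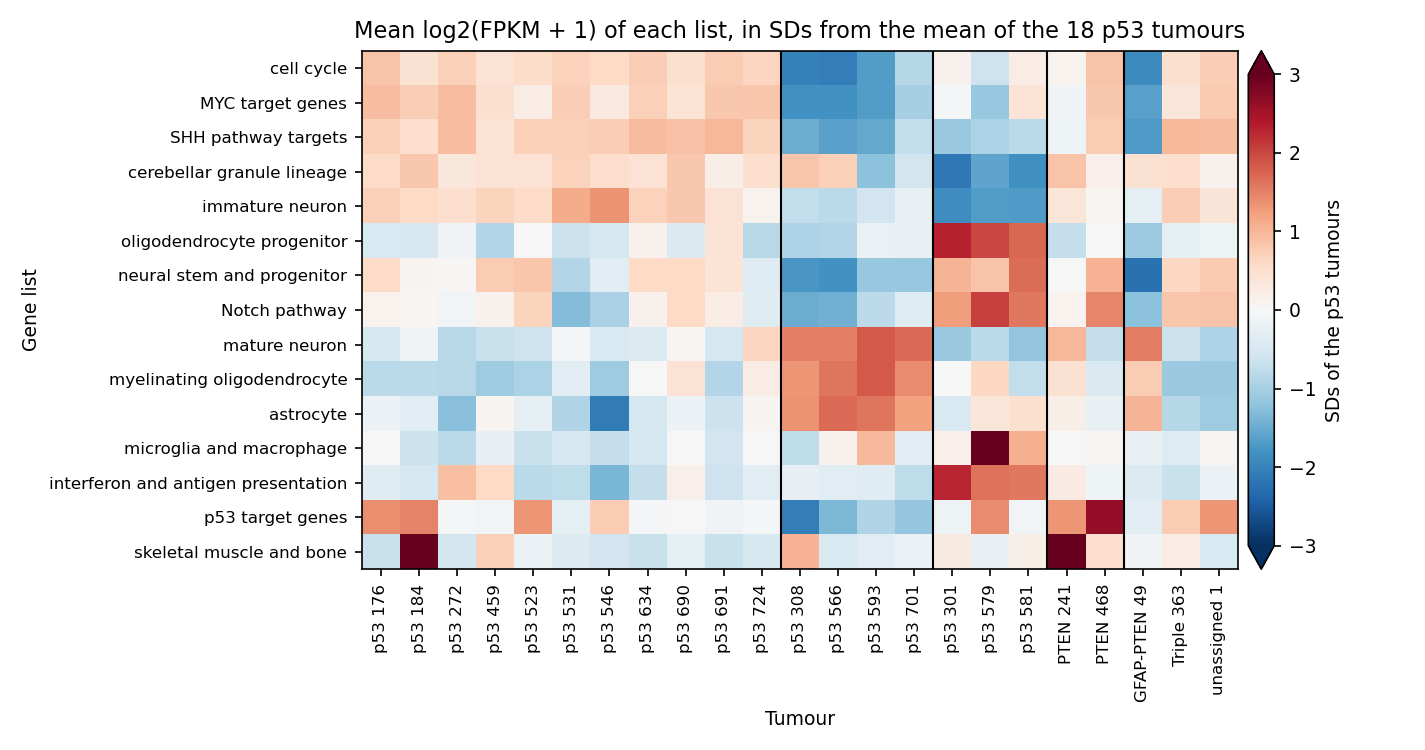
Mean log2(FPKM + 1) of 15 gene lists (rows) in each of the 23 tumours (columns), in SDs from the mean of the 18 p53 tumours, with colours limited to 3 SDs either way. Vertical lines part the p53 tumours with hedgehog markers (11), with low Mki67 (4) and with oligodendrocyte progenitor markers (3), the 2 PTEN tumours and the others.

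Among the 12 genes with the largest SD of log2(FPKM + 1) over the p53 tumours, Camk2a, Pcp2, Gng13, Snhg11 and Ptgds were highest in 1 of the 4 tumours with low Mki67. Camk2a, a kinase gene of excitatory neurons, reached 1102 FPKM in p53 593, and Ptgds, a prostaglandin synthase gene, reached 3247 FPKM in p53 566. Snhg11 reached 1116 FPKM in p53 308 and Gng13 reached 696 FPKM in p53 566. Nhlh1, Insm1 and Atoh1, transcription factor genes of neuronal precursors, were highest among the 11, at 200 FPKM in p53 523, 280 FPKM in p53 531 and 190 FPKM in p53 272, and all were lowest in p53 566. Arhgap36, known as an activator of hedgehog signalling through its inhibition of protein kinase A, split the tumours across these sets. It had 118 to 678 FPKM in p53 176, 184, 272, 634, 691, 701 and 724, and at most 6.64 FPKM in the other 11. Mir703, Mir5133 and Mir8116 were also among the 12, but FPKM is unreliable for transcripts this short.

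Foxr2 also split the p53 tumours. It had 4.34 to 24.5 FPKM in p53 184, 546, 634, 690, 691, 701 and 724, with the highest level in p53 724. It had 1.01 FPKM in p53 301 and at most 0.463 FPKM in the other 10. Both genes lie on the X chromosome, Foxr2 from 153118786 to 153132861 and Arhgap36 from 49463945 to 49500244. Of the 7 tumours with high Foxr2, 6 were among the 11 with hedgehog markers.

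**Figure D3:**
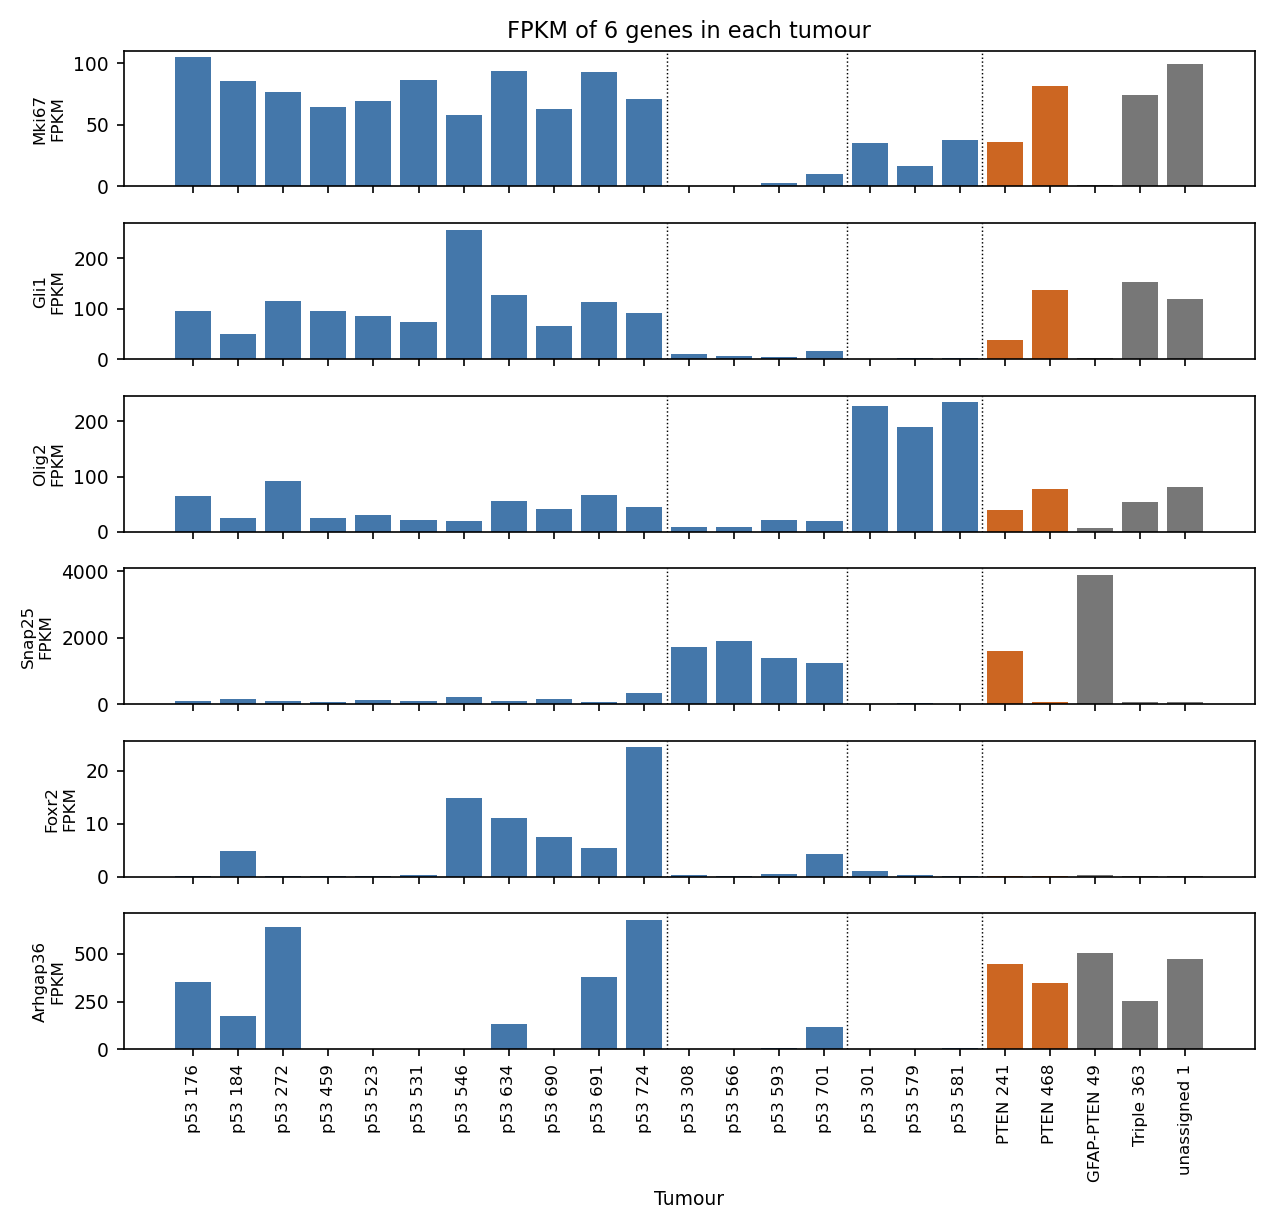
FPKM of Mki67, Gli1, Olig2, Snap25, Foxr2 and Arhgap36 (panels, bars from 0) in each of the 23 tumours, with p53 tumours in blue, PTEN tumours in orange and the others in grey. Foxr2 reached 24.5 FPKM in p53 724 and stayed at 0.137 FPKM or less in the PTEN tumours, where Arhgap36 had 445 and 350 FPKM.

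Relations between list scores were tested within the 11 tumours with hedgehog markers, and 0 of 14 passed after adjustment. Hedgehog target scores and cell cycle scores had r = 0.629 (permutation p = 0.0382, adjusted p = 0.246) and rho = 0.655 (permutation p = 0.0329, adjusted p = 0.461, n = 11). Without the 2 tumours farthest from the median hedgehog score r was 0.395, over a narrower range of scores, and within the 10 tumours titled P53 it was 0.607 (permutation p = 0.0623). MYC target scores and cell cycle scores had r = 0.646 (permutation p = 0.0361, adjusted p = 0.246) and rho = 0.582 (permutation p = 0.0662, n = 11). Here r was 0.768 without the 2 farthest tumours and 0.627 within the 10 tumours titled P53. Microglia and fibroblast scores had r = 0.563 (permutation p = 0.0527) and rho = 0.445 (permutation p = 0.172), with r = 0.210 without the 2 farthest tumours and 0.565 within the 10 titled P53. The other 9 relations over the 11 tumours had permutation p values of 0.116 to 0.985. Foxr2 was set against MYC targets (r = -0.0655, exact permutation p = 0.892, rho = -0.0286, exact p = 1.0) and against cell cycle genes (r = 0.233, exact permutation p = 0.636, rho = 0.257, exact p = 0.658) over the 6 of these tumours with at least 1 FPKM of it. These 6 are too few to leave 2 out. Without p53 690, 2 relations passed, hedgehog with cell cycle (r = 0.775) and microglia with fibroblasts (r = 0.741). The Foxr2 relations were not rerun without any of their 6 tumours, of which p53 690 is 1.

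The p53 titles are spelled in 2 ways, and the 4 tumours titled p53 (272, 301, 308 and 581) were compared with the 14 titled P53 to look for a batch. Gm10052 was at or under 0.000533 FPKM in the 4 tumours and at 8.08 to 173 FPKM in the 14 (limma adjusted p = 2.06e-04). It is annotated as a processed pseudogene on chromosome 9 from 123689233 to 123690192, identical over 960 bp to the ribonucleoprotein gene Hnrnpa1, so its value depends on how shared reads were assigned. Ibsp, the bone sialoprotein gene, averaged 4.41 FPKM (0.386 to 8.14) in the 4 tumours and 0.113 ± 0.240 FPKM (SD, n = 14) in the 14, a log2 difference of 1.99 (limma adjusted p = 0.0392). These were the 2 genes of 14916 that passed, and 1319 had an unadjusted p under 0.05, where uniform p values would give 745.8. The count was 14 without p53 272, 5 without p53 308, 1 without p53 301 and 1 without p53 581, and 995 with weights per tumour. With the 3 sets as a block it was 8, of which 7 were lower in the 4 tumours, among them the ribosomal protein genes Rpl11 (log2 difference -1.30 ± 0.14, SE, limma adjusted p = 4.34e-04), Rps29, Rpl37, Rpl24 and Rpl27. Gm10052 passed there (adjusted p = 1.34e-05) and Ibsp did not, as its log2 difference went from 1.99 ± 0.32 to 1.80 ± 0.36 (SE, adjusted p = 0.0663), a smaller difference with a larger error. The 4 tumours also had fewer estimated fragments, 12.03 to 18.5 M against 18.4 to 30.8 M. Of the 4, 1 belongs to the set of 11, 2 to the set with oligodendrocyte progenitor markers and 1 to the set with low Mki67. Against the PTEN tumours, the 14 titled P53 alone gave 0 genes past the threshold.

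GFAP-PTEN-49 expressed genes of mature neurons and glia and few genes of dividing cells, and the share from surrounding brain tissue was not tested. The p53 mean it was compared with mixes the 3 sets of p53 tumours, and the 4 with low Mki67 differed from it in the same direction in the next lists given in SD. In SD from that mean, its scores were -1.90 for cell cycle genes (-2.07 to -0.850 in the 4), 1.53 for mature neurons (1.51 to 1.84), 1.01 for astrocytes (1.21 to 1.69) and 0.757 for myelinating oligodendrocytes (1.33 to 1.85). They were -1.69 for SHH pathway targets (-1.62 to -0.733) and -1.63 for MYC targets (-1.81 to -0.985). For neural stem and progenitor genes the score was -2.24 (-1.82 to -1.13), and for oligodendrocyte progenitor genes -1.09 (-0.915 to -0.205). Glycolysis and hypoxia list scores were 5.22 in GFAP-PTEN-49 and 4.72 to 4.96 in the 4. Erythroid list scores lay apart, at 0.619 beside 1.55 to 3.73. The 4 had no common direction in cerebellar granule genes (-1.24 to 0.844, beside 0.466) or in forebrain genes, since they split by pair. In granule genes p53 308 and 566 (0.844 and 0.716) were above the p53 mean like GFAP-PTEN-49, and p53 593 and 701 below it. Forebrain list scores were 0.171 and 0.0993 in p53 308 and 566, 0.439 in GFAP-PTEN-49, and 3.32 and 3.31 in p53 593 and 701. Mki67 was at 1.11 FPKM in GFAP-PTEN-49. All 30 cell cycle genes were below the p53 mean, with a median log2 difference of -3.39 (percentile 0 of random lists). Of 14 mature neuron genes, 13 were above it, with a median of 2.95 (percentile 100), including Vsnl1 at 1117 FPKM, Slc17a7 at 913 FPKM and Snap25 at 3894 FPKM. Astrocyte genes (1.53), myelinating oligodendrocyte genes (1.39), glycolysis and hypoxia genes (1.09), immediate early genes (1.06) and cerebellar granule genes (0.63) also lay above percentile 99. In the granule list, genes of mature granule cells were high, with Gabra6 at 322 FPKM and Cbln3 at 393 FPKM, while Atoh1 was at 1.60 FPKM. SHH pathway targets (-2.17), neural stem and progenitor genes (-1.60), oligodendrocyte progenitor genes (-1.39), erythroid genes (-1.02), MYC targets (-0.94), forebrain genes (-0.81), embryonal and imprinted genes (-0.68) and WNT targets (-0.65) lay below percentile 1. The call for WNT targets ended with a pseudocount of 0.1 FPKM (percentile 3.20), as did that for embryonal and imprinted genes (3.17), and the call for erythroid genes ended with 0.01 FPKM (1.12). These are 15 of the 32 lists, and the other 17 lay inside percentiles 1 to 99. Of the embryonal and imprinted genes, 4 were above the p53 mean and 7 below. Those above included Meg3 (849 FPKM, p53 maximum 469 FPKM) and Peg3 (159 FPKM, p53 maximum 120 FPKM). Of the WNT targets, 2 were above the p53 mean and 9 below, with Notum above (13.8 FPKM, p53 maximum 2.12 FPKM).

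Of the 9784 genes with at least 5 FPKM in GFAP-PTEN-49, 1632 (16.7%) were above every p53 tumour, and of the 6735 with at least 5 FPKM in every p53 tumour, 893 (13.3%) were below all of them. When each p53 tumour was set against the other 17 in the same way, these shares were 1.20% to 21.9% above (median 6.94%) and 1.04% to 16.2% below (median 4.07%), and 1 and 3 of the 18 had shares as high. The genes farthest above were the B cell adaptor gene Blnk, at 93.6 FPKM against a p53 maximum of 6.93 FPKM, the WNT ligand gene Wnt3, at 86.8 against 8.16 FPKM, and Actn3, Phex, Rhbdl2, Mylk3, Cdh23 and Ccdc63. Those farthest below were Fxyd6, at 4.99 FPKM against a p53 minimum of 44.6 FPKM, Ly6h, Sox12, Stmn1, Nnat, Nsg2, Plxnc1 and Tmem164. Trp53 had 21.1 FPKM, Pten 20.7 FPKM, Gfap 373 FPKM, Nes 4.23 FPKM and Foxr2 0.284 FPKM, each inside the p53 range. This tumour had the lowest estimated depth of all. Gm10052 was missing from it (0.000578 FPKM), as from the tumours titled p53. Whether its differences from the p53 tumours include a library batch was not tested.

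Triple363 had expression of hedgehog, granule precursor and proliferation genes above the mean of the 18 p53 tumours, which mixes 3 sets of tumours, and at the level of the 11 with hedgehog markers. In SD from the p53 mean, its scores were 0.995 for SHH pathway targets (0.403 to 1.004 in the 11), 0.503 for the cerebellar granule lineage (0.204 to 0.820), 0.742 for immature neurons (0.112 to 1.35) and 0.492 for cell cycle genes (0.430 to 0.846). The median log2 difference from the p53 mean was 1.19 for SHH pathway targets, 1.16 for the cerebellar granule lineage, 1.16 for immature neurons and 0.78 for cell cycle genes, each at percentile 100. The hedgehog receptor gene Ptch1 reached 254 FPKM, above the p53 maximum of 183 FPKM. Notch genes (0.57), neural stem and progenitor genes (0.41), fibroblast and matrix genes (0.44), tumour driver genes (0.47) and p53 targets (0.22) also lay above percentile 99. Among the drivers, Cdk6 had 71.8 FPKM against a p53 maximum of 50.03 FPKM, and Egfr 34.0 against 25.3 FPKM. Myelinating oligodendrocyte genes (-1.67), mature neuron genes (-1.37), astrocyte genes (-0.99), erythroid genes (-0.89), glycolysis and hypoxia genes (-0.81), interferon genes (-0.72), immediate early genes (-0.64) and mesenchymal glioma genes (-0.39) lay below percentile 1. The call for p53 targets ended with a pseudocount of 0.1 FPKM (percentile 98.8), that for erythroid genes with 0.01 FPKM (1.71) and that for mesenchymal glioma genes with quantile normalization (1.09). These are 17 of the 32 lists, and the other 15 lay inside percentiles 1 to 99. Of the 17, all but Notch and myelinating oligodendrocyte genes had scores inside the range of the 11 tumours with hedgehog markers. The Notch score was 0.829 SD (at most 0.672 in the 11), and the myelinating oligodendrocyte score was -1.11 SD (at least -1.08). The other calls thus set Triple363 apart from the mixed mean and not from the 11.

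Of the 9848 genes with at least 5 FPKM in Triple363, 316 (3.21%) were above every p53 tumour, and 159 (2.36%) of the 6735 were below all of them. These shares are no excess, since 14 and 13 of the 18 p53 tumours had shares as high against the other 17. The gene farthest above was Trp73, which encodes the p53 relative p73, at 86.7 FPKM against a p53 maximum of 13.7 FPKM. It was followed by Zfp710, at 40.4 against 9.51 FPKM, Lck, Saa1, Saa2, Casq1, Setbp1 and Foxp2. The gene farthest below was Dpp6, at 2.10 FPKM against a p53 minimum of 6.0 FPKM, followed by Ddah1, Cox7c, Maea, Tstd3, Pla2g12a, Gpx4 and Pithd1. Trp53 had 87.1 FPKM, Pten 15.2 FPKM, Gfap 25.2 FPKM, Nes 70.8 FPKM and Foxr2 0.0983 FPKM, each inside the p53 range. GFAP-PTEN-49 and Triple363 were not tested against each other.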

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

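The alternatives without the 4 p53 tumours with less than 10 FPKM of Mki67, without small RNA genes and with the sets as a block were chosen after the data had been seen. No paired analysis was possible because no title number is shared between groups. Where 1 PTEN tumour was left out, the other was assumed to vary like the p53 tumours.

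The 4 genes higher in the PTEN tumours became 0 with a pseudocount of 0.1 or of 0.01 FPKM, 0 against the 14 tumours titled P53 alone, 2 with upper quartile scaling, 7 with no filter on low values and 22 with the GFAP-PTEN tumour added to the PTEN group. They became 0 with a mean of at least 5 FPKM required, where none of the 4 was tested. Leaving out 1 tumour at a time gave 0 to 18 genes, of which 1 of the 4 remained without PTEN-241 and 0 without PTEN-468. The count was 3 with quantile normalization, 4 without the variance trend, 4 with weights per tumour, 5 without the tumours with low Mki67 and 4 without small RNA genes. Apart from the filter, the cause was not tested. Trp53, Pten, Nes and Foxr2 kept their sign in each alternative run and Gfap did not, with none past the threshold.

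The 8 lists became 1 with an estimated correlation and 0 by fry. In the other alternatives 6 to 12 lists passed, and 6 to 10 when 1 tumour was left out. The cell cycle list turned to lower in the PTEN tumours with weights per tumour (adjusted p = 0.510) and with the GFAP-PTEN tumour added (0.173). The immediate early list had a mean log2 difference under 0 without PTEN-241, while its test stayed on the higher side (0.840). Leaving out 1 tumour moved its adjusted p between 0.00316 and 0.840. The cause was not tested.

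The 2 genes that differed by title spelling became 4 with a pseudocount of 0.1 FPKM, 4 with no filter, 4 with upper quartile scaling, 1 with a mean of at least 5 FPKM, 995 with weights per tumour, 8 with the sets as a block and 9 without the tumours with low Mki67. Leaving out 1 tumour titled p53 gave 1 to 14 genes. Of the 14 relations between scores, 0 passed with either pseudocount, either scaling or the 10 tumours titled P53. Without the 2 farthest tumours, where the Foxr2 relations were not run, 0 passed. The Foxr2 relations kept all of their 6 tumours when 1 tumour was left out. In that alternative 0 to 2 relations passed, with 2 without p53 690. The cause was not tested. In GFAP-PTEN-49, 13 to 15 lists and in Triple363 15 to 17 lists lay outside percentiles 1 to 99 under the 4 alternatives. Over a transcript of 960 bp, 1 fragment equals 0.0563 to 0.0866 FPKM in the tumours titled p53, so values under this are not detections.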

Other observations

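The tests of Gm10052 against depth, of the muscle genes against the PTEN title and both tests of the tumours with low Mki67 were chosen after the results had been seen, as were the list tests between title spellings. The 2 PTEN tumours differed from each other in lineage genes. PTEN-468 had 137 FPKM of Gli1, 135 FPKM of Nes, 81.8 FPKM of Mki67 and 64.6 FPKM of the neuronal gene Snap25. PTEN-241 had 37.0 FPKM of Gli1, 38.7 FPKM of Nes, 36.5 FPKM of Mki67, 1608 FPKM of Snap25 and 115 FPKM of Gabra6, a gene of mature granule cells. Both had high levels of the imprinted growth factor gene Igf2, at 180 and 120 FPKM, beside a p53 median of 29.0 FPKM and a p53 maximum of 219 FPKM. Arhgap36 was high in all 5 tumours with other titles, at 445 and 350 FPKM in the PTEN tumours, 504 FPKM in GFAP-PTEN-49, 255 FPKM in Triple363 and 472 FPKM in the tumour that could not be placed.

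Interferon and antigen presentation genes differed between the title spellings. All 18 were higher in the 4 tumours titled p53, with a median log2 difference of 1.60 (camera adjusted p = 4.29e-18, and adjusted p = 0.278 with an estimated correlation), and 16 passed when adjusted over the list alone. The highest scores of this list were in p53 301 (5.86), p53 579 (5.13) and p53 581 (5.10), the 3 tumours with oligodendrocyte progenitor markers, of which p53 579 is spelled the other way. In each of the other sets the tumour titled p53 had the highest score. Among those with hedgehog markers p53 272 had 4.35, followed by p53 459 with 4.02. Among those with low Mki67 p53 308 had 3.09, followed by p53 566 with 2.99. Of 22 sterol and fatty acid synthesis genes, 20 were lower in the 4 tumours, with a median of -0.43 (adjusted p = 5.52e-08, and adjusted p = 0.278 with an estimated correlation). In all, 10 of 32 lists passed between the spellings, and 0 with an estimated correlation. Microglia and macrophage genes were highest in p53 579, with a mean log2(FPKM + 1) of 6.36, beside at most 4.66 in the other 17 p53 tumours.

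The 4 p53 tumours with less than 10 FPKM of Mki67 may hold much brain tissue from around the tumour. Their scores for mature neurons, myelinating oligodendrocytes and astrocytes lay above the highest of the 14 other p53 tumours in 12 of 12 cases. The 4 had already been described by high Snap25 and Mbp, members of these lists, so this partly restates that description. Their microglia scores, 3.31 to 4.60, lay inside the range of the 14, 3.28 to 6.36. Depth is argued against as the whole cause, since 1 of the 4 had more estimated fragments than the median of the 14, 24.2 M. Differentiated tumours could share some of these markers, and that was not tested. The Purkinje, granule cell and forebrain markers given above differed among the 4 and were not part of these tests. GFAP-PTEN-49 also had scores above the highest of the 14 for these 3 types of cells, but was not part of these tests. Its scores were 7.36 for mature neurons, 4.62 for myelinating oligodendrocytes and 6.74 for astrocytes. The highest of the 14 were 5.58, 4.37 and 6.07. The design names no biological difference for these tumours, so no biological explanation was tested.

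Skeletal muscle next to the tumour is a candidate source of the muscle transcripts in PTEN-241 and p53 184. Over muscle genes outside the list, these were the 2 highest of the 20 tumours in 50% of those that reached 1 FPKM, 6 of 12, with Tnnc2 at 202 and 190 FPKM against at most 2.74 FPKM elsewhere and Klhl41 at 21.5 and 7.56 FPKM against at most 2.86 FPKM. In the other 6 genes another tumour was higher than at least 1 of the pair, such as Pygm at up to 41.8 FPKM, so muscle tissue stays open. The PTEN title as the source stays open too: PTEN-468 had a lower score for the list than 3 of the 18 p53 tumours, but it is a single tumour, and p53 184 was among the 3 by definition. The labels name no sort that would remove muscle.

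Gm10052 was missing from the tumours titled p53 and from GFAP-PTEN-49, at 0.000578 FPKM, and had 73.4 to 118 FPKM in the PTEN, Triple and unplaced tumours. Depth is argued against, since 93.3 fragments would be expected in the shallowest tumour titled p53 at the lowest FPKM of the other 14. Whether reads were assigned to the identical gene Hnrnpa1 instead could not be decided. In 0 of the 4 tumours did the sum of both genes lie below all 14 others, which moved reads would also give. Hnrnpa1 itself, which moved reads would raise, went both ways within the sets. It was lower in p53 272 (192 FPKM) than in every tumour of its set titled P53 (at least 208 FPKM), and so was the sum. In p53 301 and p53 581 Hnrnpa1 (182 and 158 FPKM) was above p53 579 (140 FPKM). In p53 308 it (57.1 FPKM) lay between p53 593 and p53 701 (51.5 and 75.4 FPKM). A library batch behind the spelling stays a candidate. Each set holds both spellings. With the sets as a block, 7 genes besides Gm10052 passed, and 3 of the 132 splits that keep the number of tumours per set (2.27%) gave as many, a test added after the data had been seen. Over all 3060 splits, 281 (9.18%) separated at least the 14 genes of the real one completely, where chance gives 6.94 genes. Such a share had been set beforehand as evidence against a batch, but that bound was wrong, because splits that follow the sets separate up to 2578 genes (p53 308, 566, 593 and 701 against the rest). No biological explanation was tested.

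Chance could not be excluded for the number of genes in either comparison without a block. Of 100 splits drawn from the 190 into 2 and 18 tumours, 22 gave at least the 4 genes of the real one, and the highest other gave 3021, with p53 308 and p53 566 as the pair. Of 100 splits drawn from the 3060 into 4 and 14 p53 tumours, 7 gave at least the 2 genes of the real one, and the highest other gave 5876, with p53 566, 579, 593 and 701 as the 4. Counts this far above the real ones point to a structure of the p53 tumours, since p53 308, 566, 593 and 701 form the set with low Mki67.

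The tumour that could not be placed had 119 FPKM of Gli1, 107 FPKM of Atoh1, 99.7 FPKM of Mki67, 111 FPKM of Trp53, 12.9 FPKM of Pten and 0.0450 FPKM of Foxr2. En2, a hindbrain gene, was listed at 0 in all 23 tumours, while Barhl1 and Zic1 of the hindbrain list reached 238 and 435 FPKM among the p53 tumours. Whether En2 was silent or could not be measured was not tested.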
